A study of Rattus norvegicus and Mus musculus with 10 samples.

How the data were processed

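Droplet RNA libraries were made from leukocytes of 6 compartments of naive Lewis rats (CNS, choroid plexus, dura, pia, blood and CSF; 25 rats in the study, per the labels) and from skull dura of 4 pooled naive and 3 pooled EAE mice. With the 2 BCR samples there were 10 samples, 1 per group. Per the labels' protocols, cells of CNS, pia, dura and choroid plexus were sorted on CD45 after an intravenous CD45 label, blood was separated on a gradient, and CSF was not sorted; version 2 chemistry was used for rat and version 3 for mouse, with a target of 6000 to 10000 cells. Groups were taken from the sample titles. The characteristics give EAE as condition for all mouse samples and the descriptions of the BCR samples name the opposite condition, so barcodes shared with each expression library were counted first.

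The deposited expression files hold raw UMI counts per gene and barcode for all rat and all mouse libraries, each with a cluster and a tissue or condition for most barcodes. The counts were made by the authors with Cell Ranger 3.1.0 on mm10 and Rnor_6.0, per the submitters' processing notes; the rat matrix gives version 3.0.2, per the file headers. The deposited contig tables hold UMI counts per contig, called by the authors from receptor transcripts circularised and enriched out of the same 3' libraries, per the labels' protocols. The barcodes bear this out for EAE, where 877 of 1185 occurred in the expression library, but not for the naive table, where 0 of 159 did. Gene names are those of the deposited files. Barcodes without a deposited cluster were left out of all comparisons.

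The authors' clusters were pooled into classes by name, and their leading genes were checked. The cluster named pDC was made a class of its own after its leading genes were seen. The planned comparison of the mouse B-lineage class as a whole is not reported, because most EAE cells of its cluster BcProg lack B cell markers; cluster Bc was compared instead. A cell was said to carry B cell markers at 2 or more UMIs over Cd79a, Cd79b, Ms4a1 and Ebf1 (a set reduced from the planned one after the data were seen), and to be myeloid at 10 or more UMIs of myeloid genes without them. Shares carry exact Clopper-Pearson 95% intervals. Where a share was 0, the upper limit is 3 counts of the total. The share of cells with a UMI of Rag1, Rag2, Dntt, Vpreb1 or Igll1 is the hypergeometric expectation after thinning each cell to 500 UMIs (rat) or 1000 UMIs (mouse), with shallower cells left out and groups under 20 cells not given a percent. Cells of cluster CD4 Tc (rat) and T and NK cells (mouse) served as background.

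For gene comparisons, counts were summed over the cells of a class and divided by the total (CPM). Ratios carry an exact conditional binomial 95% interval. A side at 0 was set to 3 counts over the group for log2 ratios, and its fold is given as the lower bound of its interval. Genes needed 20 UMIs over both sides. The rule for named genes, fixed before the data were examined, was the 10 highest and 10 lowest ratios by the interval bound nearest to 1, among genes with 50 CPM on the higher side, without immunoglobulin, mitochondrial, ribosomal, haemoglobin, sex-linked and unnamed genes, together with members of gene lists. The 28 lists were written beforehand; which of them the text reports was chosen after their values were seen, apart from those the design names. A list's median log2 ratio has an interval from 200 Poisson redraws, and its percentile among 10000 random lists matched on mean expression is kept as a description. The comparisons within clusters myeloid 2, Bc, CD4Tc, CD8Tc, myeloid1 and mDC2 and those of rat cluster CD4 Tc were added after the data were seen, and Ptgds, Ttr and other leading genes of those were named by the same rule. No significance test was run and no p-value is given.

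A clone is a set of barcodes with the same IGHV, IGHJ and heavy CDR3 nucleotides among productive chains. Equal numbers were drawn 100 times. Doublets were called with scrublet in scanpy 1.11.5 in each library and were kept in the values reported. The caller marked 2.89% of CSF, 1.89% of blood, 1.46% of dura, 0.552% of choroid plexus and 1.86% of EAE barcodes. In the CNS (0%), pia (0.0926%) and naive mouse dura (0.0640%) it marked too few to have worked. TMM factors came from edgeR 4.0.16 in R 4.3.3, only as a scaling alternative. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19 and matplotlib 3.10.9.

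The gene step was tested on simulated counts. For rat B-lineage cells of dura over blood (8024 genes), intervals excluded 1 for 88% of genes changed 2-fold and 100% of those changed 4-fold or 8-fold. For mouse T and NK cells (10326 genes) the shares were 89.8% and 100%. For unchanged genes, intervals excluded 1 in 4.22% and 4.25%. Both sides were drawn as Poisson counts, for which these intervals hold by construction, so these shares check the code only. They do not give the rate of false differences in the real sums, which also vary between cells and animals. Alternatives were scaling by TMM or without immunoglobulin, ribosomal and mitochondrial genes, cells weighted equally, thinning, higher minimum counts, doublets left out, other denominators and other clone definitions. Restrictions to clusters myeloid 2, CD4Tc, myeloid1, mDC2 and granulo1, to naive cells as deep as the lowest EAE cell, and to B-lineage cells without BcProg were added after the data were seen.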

Results

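Single-cell RNA libraries were made from 6 compartments of naive Lewis rats: blood, cerebrospinal fluid (CSF), the central nervous system (CNS), pia, dura and choroid plexus. The labels state 25 rats for the study. Cells of the CNS, pia, dura and choroid plexus were sorted as CD45 positive and negative for an intravenous CD45 label, which marks cells inside vessels, while blood mononuclear cells and CSF cells were not sorted. A second set held skull dura of C57BL/6 mice, 4 pooled unimmunized (naive) mice and 3 pooled mice at the peak of experimental autoimmune encephalomyelitis (EAE), each with a table of B cell receptor (BCR) contigs. Each group was 1 pooled sample, so no difference has a replicate check and every interval covers counting error only (95%). The annotated rat libraries held 9922944 UMIs in 3599 cells (CNS), 3486564 in 2272 (choroid plexus), 10083423 in 4953 (dura), 4246273 in 4039 (pia), 7317592 in 3172 (blood) and 6885992 in 3152 (CSF). Median UMIs per cell were 2704, 1318, 1705, 981, 2070.5 and 1909 in that order. The naive mouse library held 15007864 UMIs in 2776 cells (median 4163.5) and the EAE library 59256418 in 4579 cells (median 11743).

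The first question was where B-lineage cells reside in the unimmunized rat. They made up 24.4% of dural cells (1207 of 4953, 23.2 to 25.6), 38.8% of blood cells (37.1 to 40.5) and 9.20% of CSF cells (8.21 to 10.3). Shares were 1.22% in the CNS (0.890 to 1.64), 1.02% in the pia (0.729 to 1.37) and 0.748% in the choroid plexus (0.436 to 1.20). The dural share lay far above that of the other sorted tissues, whereas blood and CSF were prepared without that sort. T cells led the CSF (50.2%) and made up 25.1% of blood, 14.2% of dura, 13.02% of pia, 6.73% of choroid plexus and 1.83% of CNS cells. Macrophages and microglia made up 91.9% of CNS cells, 45.2% of pia, 25.1% of choroid plexus and 23.0% of dura. Cluster myeloid1, high in class II genes, was kept apart and made up 43.7% of choroid plexus, 33.8% of pia and 25.0% of dural cells (23.8 to 26.2), level with the dural B-lineage share, and cluster myeloid3 26.9% of blood and 15.6% of CSF. NK cells were most frequent in the choroid plexus, at 13.7%. The few CNS and pial cells in the second B cell cluster, Bc2 (36 and 26), carried no B cell markers: 0 of 36 had at least 2 UMIs of Cd79a, Cd79b, Ms4a1 and Ebf1, which allows a share of up to 8.33%, and 0 of 26 allows up to 11.5%. In dura 95.1% of that cluster's 371 cells carried them.

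**Figure D1:**
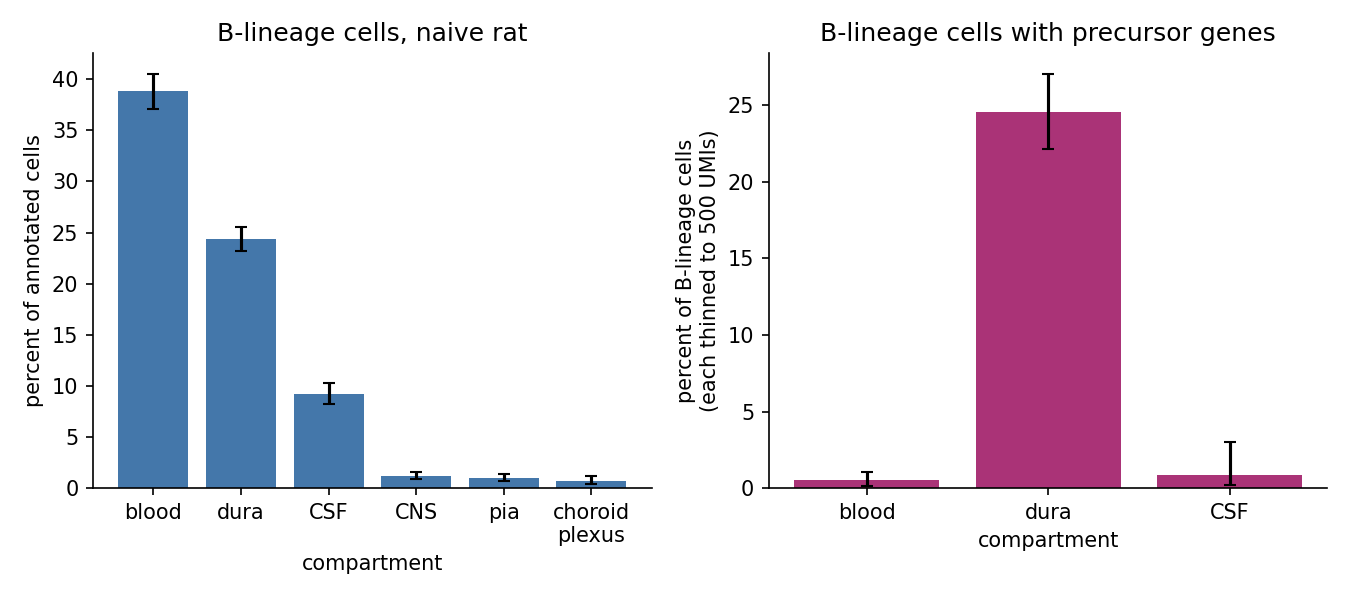
Left, percent of annotated cells in B-lineage clusters per rat compartment; right, percent of B-lineage cells with at least 1 UMI of 5 precursor genes after thinning to 500 UMIs, both with exact 95% binomial intervals and 1 pooled sample per bar. Dura reached 24.4% on the left and 24.6% on the right, against 0.524% with precursor genes in blood. CNS, pia and choroid plexus are left out of the right panel, since fewer than 50% of their B-lineage cells carried B cell markers.

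The stage of the B-lineage cells was read from Rag1, Rag2, Dntt, Vpreb1 and Igll1, which encode the recombination enzymes and the surrogate light chain of developing B cells. With each cell thinned to 500 UMIs, 24.6% of dural B-lineage cells (22.1 to 27.1) had a UMI of these genes, against 0.524% in blood (0.179 to 1.06) and 0.872% in CSF (0.214 to 2.99). Dural T cells of the cluster named CD4 Tc, which should lack them, gave 0.553% (median 1376 UMIs, against 1024 in dural B-lineage cells). In blood cells of that cluster the share was 0.0279% (2645 against 1482) and in CSF 0.0700% (2043 against 1130.5). Both dural B cell clusters held such cells, 46.7% in Bc2 and 14.7% in Bc1, the cluster that holds most blood B cells. The CNS and pial cells are given no share, because most of them carried no B cell markers.

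Against blood, dural B-lineage cells carried the genes of developing and dividing B cells and little of the mature program (1207 against 1231 cells). The median of all genes lay at a log2 ratio of 0.13, and TMM scaling moved every ratio by -0.15. All 12 measured members of the B precursor list were higher in dura (median log2 ratio 4.76, 4.13 to 5.32). Igll1 reached 1126 CPM, the UMIs of a gene scaled to a common total of UMIs, against 9.91, a 114-fold ratio (73.4 to 187), Vpreb1 232 against 4.95 (46.7-fold, 25.2 to 98.2) and Dntt 133 against 7.43 (17.9-fold, 10.6 to 32.4). Proliferation genes were higher in 17 of 18 members (median 2.99), led by Top2a at 499 against 2.48 CPM (201-fold, 85.9 to 622), and only Mcm3 was lower. Mature B cell genes were lower in 13 of 15 members (median -2.85). Cd74, the invariant chain of class II molecules, fell from 26644 CPM in blood to 2521 in dura (10.6-fold lower, 10.2 to 10.9), Ms4a1, which encodes CD20, was 11.03-fold lower (9.10 to 13.5) and Ccr6 18.1-fold lower (11.7 to 29.5). Cd79a differed little, at 3110 against 3421 CPM, with a sign that changed when cells were weighted equally, while the pan-B list as a whole had a median of -1.35. Cxcr4 was 23.6-fold higher in dura (16.1 to 36.2), as it was in dural cells of the cluster named CD4 Tc (25.6-fold, 16.8 to 40.6).

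**Figure D2:**
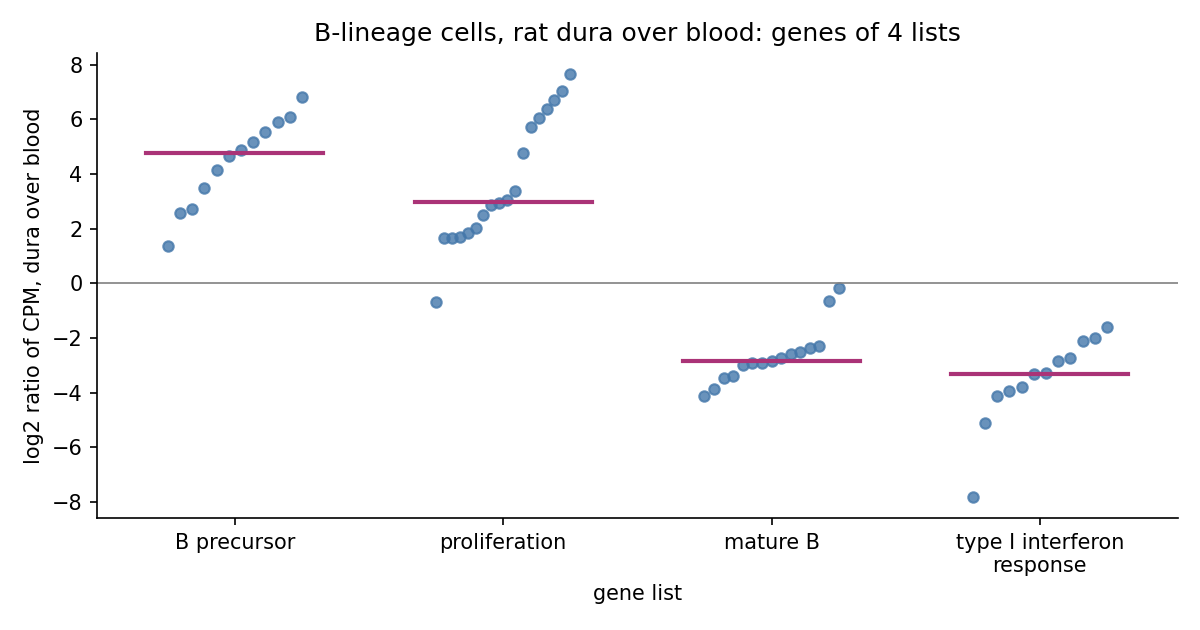
Each point is 1 gene's log2 ratio of CPM in summed B-lineage cells, rat dura over blood, with a line at the median of each gene list. The precursor and proliferation lists centre at 4.76 and 2.99, the mature B and type I interferon lists at -2.85 and -3.32.

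Interferon genes were lower in the dural cells. All 12 measured type I interferon response genes lay below blood (median -3.32, -3.72 to -2.85): Mx1 was at 7.47 against 257 CPM (34.4-fold lower, 19.95 to 65.1) and Isg15 was 9.84-fold lower (5.46 to 19.5). Interferon gamma response and antigen presentation genes had a median of -1.76, with RT1-Da, a class II gene, 6.04-fold lower (5.74 to 6.36). Within cluster Bc1 alone (836 dural, 1226 blood cells) the precursor list kept a median of 4.25 and the mature list one of -2.06, with Rag1 at 77.4 against 0.997 CPM and Cd74 5.92-fold lower (5.73 to 6.12). Genes of handling and of other cell types were higher as well. Dissociation stress genes were higher in all 11 members (median 2.50, for example Jun at 711 against 42.6 CPM), and inflammatory genes had a median of 2.83, with Ccl2 at least 126-fold higher. Border macrophage genes had a median of 4.02: Apoe was at 1861 against 0.495 CPM, and dural T cells held 1417, NK cells 2334 and dural macrophages 75125 CPM of it.

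Macrophages of the borders were compared with those of the CNS. The dural cells (1139) lay mostly in cluster myeloid 2 (1033) and the CNS cells (3306) mostly in the microglia cluster, with 332 in myeloid 2, so part of the difference is that of the clusters. All-gene medians were -0.27 (dura) and -0.33 (pia). Microglia genes had a median log2 ratio of -4.06 in dura (10 of 11 lower) and -3.58 in pia (11 of 11 lower), and border-associated macrophage genes one of 6.67 and 5.76, with all 11 higher in both. Mrc1, a scavenging lectin receptor, was at 1513 CPM in dura and 1418 in pia against 1.45 in the CNS. Cd163, a haemoglobin scavenger receptor, was at 704 and 932 CPM against 0, at least 1707-fold and 2258-fold higher. The microglial gene Tmem119 was 193-fold lower in dura (135 to 287) and 40.6-fold lower in pia (33.2 to 50.05). Choroid plexus macrophages were 162 cells of the microglia cluster and 409 of myeloid 2, a larger part of the former than in dura (106 of 1139). They had an all-gene median of -0.39 that TMM scaling moved by 0.15. Tmem119 was at 142 CPM, 15.1-fold below the CNS (12.6 to 18.1), with a log2 ratio of -3.92 in the whole class and within myeloid 2 alone, and they carried 4719 CPM of the epithelial transcript Ttr. Class II genes were higher in dural macrophages, with Cd74 at 6928 against 238 CPM (29.1-fold, 27.9 to 30.5), although the interferon gamma list as a whole had a median of 0.50. B cell transcripts were present too: the pan-B list had a median of 5.66, with Cd79a at 58.2 against 0.447 CPM.

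The same split held within cluster myeloid 2 (all-gene median -0.22, moved by 0.36 under TMM scaling), where the border list had a median of 5.08, Mrc1 was 177-fold higher in dura than in the CNS (85.9 to 441) and Tmem119 275-fold lower (166 to 493). The interferon gamma list, at -0.31, did not keep its direction there. Dural and pial cells of this cluster also differed from each other. Cd209f, a C-type lectin gene, was 92.8-fold higher in dura (31.6 to 452), the eosinophil attractant Ccl24 3.61-fold (3.26 to 4.01) and the iron exporter Slc40a1 4.93-fold (3.67 to 6.75). Ptgds, made by leptomeningeal cells, was 28.7-fold lower in dura (21.4 to 39.3) and Ttr 109-fold lower (55.1 to 254).

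In the mouse, the question was how dural cells differ at the peak of EAE. Neutrophils made up 5.22% of naive cells (4.43 to 6.12) and 23.5% of EAE cells (22.3 to 24.8), macrophages and monocytes 9.94% (8.85 to 11.1) and 32.3% (31.0 to 33.7), and dendritic cells 10.1% and 21.5%. Lower in EAE were T and NK cells (39.9% and 15.9%), innate lymphoid cells (ILC; 18.3% and 1.16%), mast cells (8.43% and 0.415%) and B-lineage cells (6.45%, 5.56 to 7.43, and 2.40%, 1.98 to 2.89). The lowest EAE cell had 5722 UMIs and the lowest naive cell 503, which can set these shares. Among the 739 naive cells that reached 5722 UMIs, neutrophils were 4.33% (2.98 to 6.06) and ILC 5.41% (3.89 to 7.30), so both differences kept their direction. T and NK cells were 16.1% there (13.5 to 19.0), level with EAE. Macrophages were 27.3% (24.1 to 30.7), dendritic cells 32.6%, above EAE, and B-lineage cells 5.95% (4.36 to 7.91). Mast cells were 2.30% (1.35 to 3.66), still above EAE. With the minimum scaled to the depth of naive macrophages (4005 UMIs), T and NK cells were 38.1% (35.6 to 40.6), near the full naive share. Dendritic cells then lay below EAE. How T and NK cells and dendritic cells compare with EAE therefore depends on how the minimum is set. Macrophages stayed below EAE under both minimums, and B-lineage and mast cells above it. Plasmacytoid dendritic cells, kept apart, were 1.73% and 2.75%.

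**Figure D3:**
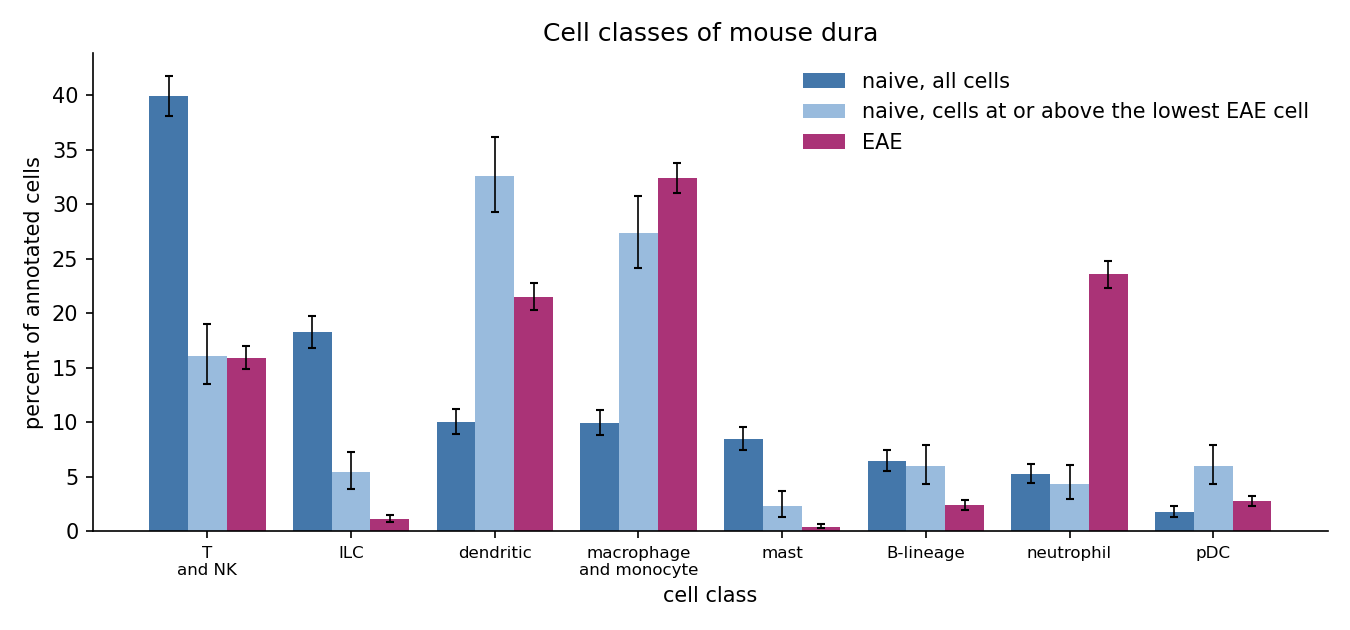
Percent of annotated mouse dural cells per cell class, with exact 95% binomial intervals and 1 pooled sample per condition, for all naive cells, naive cells with at least 5722 UMIs and EAE cells. Neutrophils stay below the EAE level of 23.5% in both naive sets, while T and NK cells of deep naive cells (16.1%) match EAE (15.9%). With the minimum scaled to macrophage depth, T and NK cells were 38.1% of naive cells.

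T and NK cells in EAE (727 against 1108) carried more transcripts of cell division and the interferon response. The make-up of the class differed too: CD4 cells went from 353 to 152, CD8 cells from 240 to 226, gamma delta T cells (gdTc) from 379 to 79 and Treg cells from 30 to 116. The all-gene median was 0.12. Proliferation genes were higher in 20 of 21 members (median log2 ratio 2.15), with Mki67 at 75.4 against 3.87 CPM (19.5-fold, 12.2 to 33.2) and the histone gene Hist1h2ap 54.4-fold higher (42.4 to 71.1). Type I interferon genes had a median of 0.76 and interferon gamma genes one of 0.82, with Ifitm3 9.53-fold higher (8.13 to 11.2), although Isg15 was 2.26-fold lower (2.04 to 2.51). Tissue residency genes moved down (median -0.46): Cxcr6 was 2.99-fold lower (2.82 to 3.17). The cytokine genes Csf2 and Il17a were 41.6-fold (30.0 to 59.4) and 9.60-fold lower (8.68 to 10.6). Within CD4 cells alone Csf2 stayed 47.2-fold lower (30.1 to 78.8), whereas Il17a and Cxcr6 were not lower (log2 ratios 0.29 and 0.18), so the class values of these 2 genes do not show a fall within that cluster. In CD8 cells alone, however, Cxcr6 was 6.44-fold lower (5.09 to 8.23), at 51.7 against 333 CPM. Csf2 also leads in the ILC cluster, and it was lower in EAE cells of cluster Bc (0 against 165 CPM) and in neutrophils (0.416 against 85.7 CPM). Its difference was thus not particular to CD4 cells, and its source was not tested. Proliferation genes had a median of 1.92 in CD4 and 0.08 in CD8 cells. In the class as a whole, inflammatory genes had a median of -0.52. Neutrophil transcripts were higher in all 14 members (median 4.64), with S100a8 at 2284 against 56.5 CPM. Whether the interferon difference belongs to the T and NK cells or to RNA of other cells was not tested. All 14 dissociation stress genes were lower (median -1.75), Hspa1b by 88.5-fold (59.3 to 139).

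EAE macrophages and monocytes (1481 against 276) carried more monocyte and type I interferon response transcripts and fewer of inflammatory chemokines. Cluster myeloid2, which leads in Vcan, went from 49 to 481 cells of the class. The all-gene median was 0.30, and TMM scaling moved ratios by -0.19. Monocyte genes had a median of 0.99, with Ly6c2 3.56-fold (3.29 to 3.85), Chil3 5.37-fold (5.00 to 5.78) and Vcan 6.25-fold higher (4.66 to 8.59). Arg1 was at 70.6 against 0.452 CPM (156-fold, 28.0 to 6181), and Saa3, an acute phase gene, at 307 against 0.452 (680-fold, 122 to 26853). Type I interferon response genes had a median of 0.93, whereas the interferon gamma list (0.20) lay below the all-gene median and held members both ways: Gbp2 was 5.83-fold higher (4.74 to 7.24) and the class II gene H2-Aa 1.76-fold lower (1.73 to 1.78). Inflammatory genes were lower in 14 of 17 members (median -1.74), with Cxcl2 5.87-fold (5.75 to 5.99) and Ccl4 5.73-fold lower (5.54 to 5.92), while Ccl5 was 3.04-fold higher (2.79 to 3.31). Retnla was at 0.109 against 214 CPM (1964-fold lower, 541 to 16268). Within cluster myeloid1 alone (1000 against 227, all-gene median 0.40) the monocyte list had a median of 2.04, the type I list 1.14, the interferon gamma list 0.30 and the inflammatory list -1.54, with Chil3 85.7-fold higher (45.1 to 188). The type I interferon gene Ifnb1 itself was lower in EAE there, at 0.413 against 61.9 CPM (150-fold, 62.3 to 471). Stress genes of the class had a median of -0.86, and all 15 neutrophil genes were higher (median 4.25, S100a8 at 3195 against 59.6 CPM). Whether RNA of other cells adds to the interferon difference was not tested.

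Dendritic cells in EAE (985 against 279) carried more transcripts of the type I interferon response. Cluster myeloid3, which leads in Fscn1, went from 23 to 281 cells of the class. The all-gene median was 0.49 and TMM scaling moved ratios by -0.35. Type I interferon genes were higher in 13 of 16 members (median 1.02) and interferon gamma genes had a median of 0.70, with Ly6a 43.1-fold higher (33.8 to 56.1). Ccr7 and Fscn1 were 2.10-fold (2.01 to 2.21) and 3.66-fold higher (3.34 to 4.01), and Cd209a was 6.33-fold lower (6.01 to 6.67). Inflammatory genes were lower in 15 of 16 members (median -1.73), Il6 by 14.2-fold (10.2 to 20.2). Within cluster mDC2 alone (563 against 176, all-gene median 0.55) Ccr7 was level, at 422 against 428 CPM, and the Fscn1 interval included 1 (1.66-fold, 0.924 to 3.24). The type I list had a median of 1.24 there and the interferon gamma list, at 0.46, lay below the all-gene median. Neutrophil transcripts had a median of 4.72 and stress genes one of -0.99. Whether RNA of other cells adds to the interferon difference was not tested here either.

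Neutrophils in EAE numbered 1078, against 145 in naive dura, of which the dividing cluster granuloProli held 143 and 7. The all-gene median was -0.36 and TMM scaling moved ratios by 0.53. Hist1h2ap was 15.4-fold (12.2 to 19.7), the granule genes Lcn2 and Ltf 2.30-fold (2.24 to 2.35) and 2.20-fold (2.12 to 2.28) and Ifitm1 6.38-fold higher (5.29 to 7.76), while the neutrophil list as a whole had a median of 0.16. Within cluster granulo1 alone these 4 genes kept their direction (log2 ratios 3.90, 1.06, 0.92 and 3.02). Inflammatory genes had a median of -2.002, with Cxcl2 7.98-fold (7.51 to 8.48) and Il1b 5.28-fold lower (4.91 to 5.67), and stress genes one of -2.07. The type I interferon list (-0.21, -0.52 to 0.24) has an interval that includes 0, and its sign changed under TMM scaling (0.31) and above the lowest EAE cell (0.83). The interferon gamma list, at -0.39, also changed sign under TMM scaling (0.14). Among the 32 naive neutrophils at or above the lowest EAE cell, the inflammatory list (0.019) and Cxcl2 (log2 ratio 0.11) were no longer lower in EAE. Naive neutrophils also held transcripts of other cell types, such as stromal Igfbp5 at 116 against 0.178 CPM.

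Mouse naive dura also held B-lineage cells with precursor genes. With each cell thinned to 1000 UMIs, 9.92% of naive B-lineage cells (6.10 to 15.5) had a UMI of the 5 precursor genes, all in the cluster named BcProg (19.2%), against 0.180% of T and NK cells (median 4026.5 UMIs, against 3056 in B-lineage cells). None of 73 cells of cluster Bc had one, which allows up to 4.11%. The EAE B-lineage cells are given no share, because most of them carried no B cell markers. The BcProg cells were not alike in both conditions: 88 of 92 naive cells (95.7%) carried B cell markers and 7 of 74 EAE cells (9.46%, 3.89 to 18.5). The other 67 EAE cells passed the cut of 10 UMIs of myeloid genes. That cut is not scaled to depth (median 23693 UMIs), and EAE T and NK cells held 2284 CPM of the neutrophil gene S100a8. The count therefore does not show that these cells are myeloid. Summed, EAE BcProg cells held 1204 CPM of Prtn3 and 414 of Elane, against 28.0 and 8.60 in naive. Without BcProg, B-lineage cells were 3.24% of naive and 0.799% of EAE cells. Within cluster Bc (25 EAE and 74 naive cells), all cells carried B cell markers, and the all-gene median of -0.24 was moved by 0.22 under TMM scaling. The EAE cells of this cluster were higher in all 5 measured type I interferon genes (median 2.24), with Ifitm3 30.5-fold higher (14.5 to 76.8), and the interferon gamma list (median 0.89) had 9 of 13 members higher and 3 lower. Among them Psmb8 was 3.92-fold (2.78 to 5.65) and H2-Ab1 2.11-fold higher (1.89 to 2.35), and Irf1 2.55-fold (1.43 to 4.76) and B2m 1.51-fold lower (1.31 to 1.74). The precursor gene Vpreb1 was at 188 against 0 CPM, at least 12.4-fold higher, yet only 1 of the 25 EAE cells held a UMI of the 5 precursor genes (4.00%, 0.101 to 20.4). The pan-B genes had a median of -0.78. Myeloid genes summed to 20182 CPM in EAE cells of cluster Bc against 2212 in naive, with S100a8 at 5558 against 47.2 CPM. The T cell gene Trbc2 was 11.7-fold higher (4.25 to 44.6). Ifitm1 was at 881 CPM, near the 1012 CPM of EAE neutrophils. Whether the interferon difference belongs to the B cells or to RNA of other cells was not tested. Of stress genes, Hspa1b was at 0 against 142 CPM, while Jun was not lower (1.21-fold, 0.859 to 1.71).

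The BCR tables addressed whether dural B cells form clones. No naive BCR barcode of 159 occurred in the mouse expression libraries, which allows up to 1.89%, whereas 5 occurred in the rat libraries, near the 5.87 expected from a common barcode list, and the naive expression library shared 1 barcode with them against 115 expected. The naive table was therefore not shown to come from the naive library, and its values describe the table alone. The naive table held 92 barcodes with a productive heavy chain in 21 clones, and 80 of them (87.0%, 78.3 to 93.1) lay in clones of at least 2. The top clone had 26 barcodes and used IGHV1-72 with IGHG2B. IGHA took 63.0% of heavy chains, IGHG2B 30.4% and IGHM 6.52%, and lambda light chains 46.9% of barcodes. In EAE, 257 of 340 barcodes (75.6%, 70.7 to 80.1) lay in clones, 74.0% when 92 barcodes were drawn. The top clone had 94 barcodes with IGHV8-8 and IGHA. IGHM took 55.3%, IGHA 38.5% and IGHG2C 4.71%, and lambda chains 1.04%. With each clone counted once, lambda chains were 18.2% in the naive table and 4.10% in EAE. Median heavy CDR3 length was 13 residues in the naive table and 15 in EAE, and 0 clones were shared. Of 1185 EAE barcodes 877 (74.0%) occurred in the EAE library. There, only 23 heavy chain barcodes lay in B-lineage clusters, of which 11 (47.8%, 26.8 to 69.4) were in clones, and 177 lay in other clusters, 174 of them (98.3%) in clones. With clones counted only among the 23, the share was 6 of 23 (26.1%).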

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

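All tests in this part were chosen only after the results were seen, and the rules of the cell cycle and heavy chain tests were changed again after their first values were known. The signals listed first came from barcodes without a deposited cluster, which enter no comparison, and were picked because a gene exceeded 1000 CPM and 5 times its level in annotated cells, in libraries with at least 200 such barcodes. In CSF, Ttr, a transcript of choroid plexus epithelium, reached 146681 CPM in 4348 barcodes, and in pia 8582 CPM. In mouse EAE dura the genes of immature neutrophils Elane, Prtn3 and Mpo reached 5911, 5903 and 2700.0 CPM, and in naive dura Elane and Prtn3 reached 1241 and 1110 CPM. Red cell transcripts were high in naive mouse dura (Hbb-bs 14552 CPM, Hba-a1 7846 CPM) and in rat dura (Hbb 5648 CPM).

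The B cell clusters BcProg (mouse) and Bc2 (rat) held cells without B cell markers in mouse EAE dura, rat CNS and rat pia. B cells that picked up myeloid RNA from doublets or free RNA would keep their markers, and only 9.46% of EAE BcProg cells had them (3.89 to 18.5) against 95.7% in naive, at a higher median depth, which argues against that source. Cells of other types that were grouped by cell cycle genes may account for EAE BcProg and pial Bc2, where proliferation genes summed to 14791 and 10092 CPM against 2106 and 616 CPM in macrophages of the same tissue. In the rat CNS their sum was 1363 against 746 CPM, while Mki67 was at 101.7 (33.03 to 237, 5 UMIs) against 1.90 CPM, so their grouping stays open. An effect of disease was not tested apart from these, and the rat compartments show that such cells also occur without it.

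Cell shares differed between EAE and naive mouse dura. The EAE library held 5000 barcodes and the rat CSF library 7500, both round numbers, against 3126 in naive dura. Whether a set number of barcodes was kept was not tested. The lowest EAE barcode had 5722 UMIs, a minimum that the naive library (lowest 491) lacks. Applying that minimum to naive cells left neutrophils at 4.33%, and 3.89% with the minimum scaled to macrophage depth, far below the 23.5% of EAE, which argues against it as the whole cause. ILC at 5.41% and 16.2% stayed above the 1.16% of EAE, with part of the fall open. For T and NK cells the minimum gave 16.1%, level with EAE, and the scaled one 38.1%, near the full naive share, so the minimum and the disease cannot be told apart. The pools also differ in sex, since Xist was at 273.9 CPM in the naive pool (266.0 to 281.9) with Y-linked Ddx3y at 14.6 CPM, and at 0 in EAE, and with 1 pool per condition disease and sex cannot be told apart.

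In EAE, heavy chains in clones sat mostly on barcodes outside the B cell clusters. Doublets with B cells would bring antibody transcripts, yet barcodes with an IGHA contig had 8.43 CPM of Igha (4.04 to 15.5), like the 10.3 CPM of cells without a heavy chain, and only 8.45% of IGHM barcodes (3.16 to 17.5) reached the lower quartile of Ighm UMIs of B-lineage barcodes, so doublets are not the source of most. Free RNA would give contigs and transcripts together, yet 98.8% of these barcodes (95.6 to 99.9) had more contig than transcript UMIs, against 31.8% in B-lineage clusters (13.9 to 54.9). Whether contigs were joined to barcodes of other cells during the enrichment stays open: 97.8% of the IGHA barcodes (92.4 to 99.7) lay in clones against 3 of 4 in B-lineage clusters, too few to compare, and of the IGHM barcodes 98.6% did against 44.4% (21.5 to 69.2), but Ighm was at 162.8 CPM (138.5 to 190.0) against 95.9 in cells without a heavy chain. Whether B cells expand in EAE stays open: with clones counted only among B-lineage barcodes 26.1% of these lay in clones (10.2 to 48.4), with clones counted over all barcodes 47.8% (26.8 to 69.4), and the naive table has none to compare.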

How the results depend on the processing

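The restrictions to clusters myeloid 2, CD4Tc, myeloid1, mDC2 and granulo1, to naive cells at or above the lowest EAE cell (also with that minimum scaled to macrophage depth) and to B-lineage cells without BcProg were chosen only after the results were seen. There were no replicates to leave out. No paired analysis was possible because each group is 1 pooled sample. The naive BCR table gave no value within B-lineage clusters, and leaving out called doublets tests little in the CNS, pia and naive mouse dura. Of 196 alternative values of the main results 137 stayed within their interval, 58 moved and 1 changed sign; of 603 values of the other results 411 stayed, 184 moved and 8 changed sign. These sign counts leave out results whose own interval includes 0, such as the neutrophil type I list, which also changed sign. Of 465 alternative values of single genes 458 kept their direction. Where a value moved, the cause was not tested unless the setting itself shows it. TMM scaling shifted the rat dura over blood mature B list to -3.00 and, in EAE over naive, the macrophage interferon gamma list to 0.014, the dendritic type I list to 0.67 and interferon gamma list to 0.36, and the neutrophil type I list to 0.31 and interferon gamma list to 0.14, both with a changed sign. Weighting cells equally gave -2.41 for the mature B and 2.47 for the proliferation list of rat B-lineage cells, 0.061 for their Cd79a (sign changed), 0.30 and -0.83 for the interferon gamma lists of mouse macrophages and neutrophils, and 0.87 for the dendritic type I list. Thinning to 1000 UMIs gave 0.36 for the macrophage interferon gamma list. Cluster Bc1 alone gave -2.06 for mature B, 1.71 for proliferation and 0.25 for Cd79a (sign changed). Cluster myeloid 2 alone gave border lists of 5.08 (dura) and 3.83 (pia), a pial microglia list of -3.99 and a dural interferon gamma list of -0.31 (sign changed). In CD4Tc alone Cxcr6 was 0.18 and Il17a 0.29, and in mDC2 alone Ccr7 was -0.020 (all 3 with a changed sign) and the interferon gamma list 0.46. In myeloid1 alone the type I list was 1.14 and the interferon gamma list 0.30. In neutrophils above the lowest EAE cell the type I list was 0.83, the inflammatory list 0.019 and Cxcl2 0.11, all with a changed sign, and the interferon gamma list -0.17. B-lineage shares from markers per cell were 0.306% (CNS), 0.421% (pia) and 44.1% (blood). Precursor-gene shares follow depth by construction: without thinning they were 38.4% (rat dura), 1.38% (blood) and 21.8% (naive mouse), at 300 UMIs 18.6% (rat dura), and at 500 UMIs 5.72% (naive mouse); without BcProg the naive mouse share was 0%. Without BcProg B-lineage cells were 3.24% (naive) and 0.799% (EAE). Leaving neutrophils out of the denominator raised T and NK cells to 42.1% (naive) and 20.8% (EAE), and in EAE B-lineage cells to 3.14%, macrophages to 42.3%, dendritic cells to 28.1% and ILC to 1.51%. Naive cells above the lowest EAE cell were 16.1% T and NK, 27.3% macrophage, 4.33% neutrophil, 32.6% dendritic, 5.41% ILC and 2.30% mast cells. With the scaled minimum these were 38.1%, 14.6%, 3.89%, 17.0%, 16.2% and 3.15%, and B-lineage cells 3.89%. Naive mast cells at 1000 UMIs were 6.15%. Barcodes in clones were 94.6% (naive) by CDR3 residues alone, 59.0% (naive) and 68.1% (EAE) by heavy and light CDR3, and 26.1% within EAE B-lineage clusters; with each clone once, lambda chains were 18.2% (naive) and 4.10% (EAE).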

Other observations

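The comparisons in this part were chosen after the data were seen. The rat cluster named CD4 Tc was compared between dura and blood (591 against 740 cells). It held more Cd8a than Cd4 in both, at 126 against 5.39 CPM in dura and 440 against 15.0 CPM in blood. Cd8a was 3.48-fold lower in dura (2.87 to 4.26). The make-up of the cluster may therefore differ between the sides, which was not tested, and part of what follows can come from that. The residency list had a median log2 ratio of 1.55, with Cxcr6 44.1-fold and Cd69 5.36-fold higher, while Lef1 was 22.1-fold lower. Il17a was at 175 against 0.483 CPM (362-fold, 64.0 to 14375), Rora 61.6-fold higher and Gata3 3.23-fold higher. Macrophage transcripts came with them, with C1qa at least 108-fold higher, as did dissociation stress genes (median 2.75).

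In CSF, B-lineage cells and those of cluster CD4 Tc carried transcripts of brain and choroid plexus. Ttr was at 30155 CPM in B-lineage cells against 0.495 in blood, and at 20695 CPM in CD4 Tc cells against 0. S100b reached 1014 and 662 CPM, and Pcp2, a Purkinje cell gene, was at least 247-fold and 171-fold higher. Lower in both were Tomm6 (14.2-fold and 14.0-fold) and Btf3 (18.9-fold and 12.9-fold). The all-gene medians over blood were -0.39 and -0.32, which TMM scaling moved by 0.19 and 0.34.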
